A study of Mus musculus with 6 samples.

How the data were processed

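Total RNA from 6 whole mouse embryos at day 12, 2 each of wild type, heterozygous and homozygous genotype for a STAT3 allele altered at 2 residues, was measured per the labels on 1-colour Agilent arrays after amplification and Cy3 labelling. Genotypes and replicate numbers were taken from the sample titles. The labels name tumor tissue in the extraction protocol and call the wild-type genotype a mutant in one field, and the titles were followed here. Litters were not given in the sources used here, beyond the statement that embryos of the genotypes came from the same womb. Sex-linked transcripts differed between the 2 wild-type embryos and between the 2 homozygous embryos, so these were separate embryos.

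Per the file headers, the deposited scanner files hold intensity values and per-spot flags from Feature Extraction 11.0.1.1, background-subtracted and detrended within each array, with low values replaced by a surrogate above 0 and no normalization between arrays. The authors also deposited a table of log2 values with the same median, 6.73, in every array, and the tool and method of that normalization are not given in the sources used here. These values correlated at 0.995 or more with the intensities of their own array. The median signals of spots and their local background, also intensity values per the file headers, were used for an alternative background correction and for array quality.

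Each array held 44397 spots, of which 43020 measure genes and 1377 are controls. Control spots and spots marked as outliers were left out, and spots of the same probe were averaged, which gave 39429 probes. No spot was saturated. The processed intensity was log2 transformed and the 75th percentile of the array subtracted. Probes well above background on both arrays of at least 1 genotype were kept (29906). Probe accessions were matched to gene names through a RefSeq gene table of the GRCm38.p6 assembly, used for names only, while the array was annotated to the mm9 build. This named 27234 probes (69.1%) with 20659 symbols and left 12195 without a name, tested under their own identifiers. A gene was represented by its kept probe with the highest mean over the 6 arrays, which gave 24572 tested genes, 16979 with a symbol and 7593 without. Because a difference between homozygous embryos and the others was measured against another slide, no correction for slide could be made.

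All 6 arrays were fitted in 1 linear model of genotype with limma 3.58.1 in R 4.3.3, with moderated t-tests (3 residual and 3.23 prior degrees of freedom). The 3 comparisons were homozygous against wild type, heterozygous against wild type and homozygous against heterozygous. Genes passed at a Benjamini-Hochberg adjusted p below 0.05 within each comparison, with no minimum fold change, and a moderated F-test covered any genotype difference. The number of genes past an unadjusted p below 0.05 was 10681, 540 and 10066 in these comparisons. Gene lists (31 with 814 members) were tested with camera at a preset correlation of 0.01. Of these, 29 were tested, each with at least 5 measured members, while embryonic globins, with 4, and sex-linked markers are given as values. Camera's preset correlation treats members of a list as nearly independent, so it was set beside camera with an estimated correlation and beside fry. With an estimated correlation, camera judges a list on the 3 residual degrees of freedom, so almost no list could pass here. A call lost in this way therefore does not by itself show that members of a list vary together. Members of a list are also given as passing over all genes or adjusted over the list alone. The tests, lists, alternatives and rule for named genes were chosen before the data were examined, with 1 departure. The planned normexp correction named the mean spot signal, which the deposited files lack, and the median spot signal was used in its place.

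Genes were named by rule. In each comparison these were the 10 largest changes in each direction among genes with a symbol other than a clone, predicted or numbered locus, an accession or a probe identifier, that passed the test with both arrays of 1 genotype beyond both of the other. Where fewer than 10 passed, those with the smallest unadjusted p completed the 10 as values only. Stat3 and up to 4 members with the smallest p of each list described were added. This gave 20 genes per comparison, and none of them passed in the heterozygous against wild type comparison. A result of the homozygous comparisons is not reported here. Saa2, Iigp1 and members set beside another list member were singled out after their values were seen, as were the genes given as examples of concordant or discordant probes.

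Tested on simulated data with the same number of arrays and genes, the fit recovered 4.48%, 53.7% and 95.5% of genes changed 1.5-, 2- and 4-fold in the homozygous against wild type comparison. The corresponding shares were 1.49%, 47.8% and 98.5% for heterozygous against wild type, and 1.49%, 53.7% and 98.5% for homozygous against heterozygous. Of the unchanged genes 7, 8 and 11 were called. Only 67, 67 and 66 genes were changed by these folds in each simulation. In that of homozygous against wild type 109 genes were called in all, against 7110 in the real comparison. With more genes called the adjusted threshold is less strict, so the shares do not describe the sensitivity of the real homozygous comparisons. A list shifted in the simulation was recovered in each comparison, with 0 other lists called. The simulated genes varied independently, while the estimated correlation of the real lists reached 0.71 for lens crystallins. The simulation therefore does not show how often camera calls lists whose members vary together.

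Comparisons against the same wild-type arrays share their chance deviations, so the correlation of heterozygous and homozygous differences was set beside 100 simulations with no genotype effect. For genes with at least 2 kept probes (4435), the fold changes of the brightest and second brightest probes were compared. Alternatives covered quantile normalization, normexp background correction (offset 50, computed on median spot signals) with either normalization, the authors' log2 values, the filter on dim probes, the choice of probe, the arrays in the fit, the replicate number as a block, eBayes with trend and robust, array weights with statmod 1.5.0, thresholds, the number of mutant alleles as a linear term, and leaving out each array in turn. A test of the second brightest probe and a count of genes with all probes called in one direction were added after the data were seen.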

Results

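Gene expression was measured in whole mouse embryos that differed in the Stat3 gene, which codes for a transcription factor activated by cytokines of the interleukin family. The mutant allele alters STAT3 at 2 nearby residues, where its name gives arginine in place of lysine. Per the labels, embryos at day 12 were wild type, heterozygous or homozygous for this allele and came from the same womb, with 2 embryos per genotype, and the study addressed how the allele affects development. Total RNA of each embryo was hybridised to 1 array of a 1-colour Agilent mouse design, giving 6 arrays. The wild-type arrays had 76.2% and 75.4% of their gene probes well above background, the heterozygous arrays 75% and 77.3%, and the homozygous arrays 73.4% and 70.7%. The 75th percentile of the signal was 1037 and 1067 in the wild-type arrays, 1187 and 1263 in the heterozygous arrays, and 860 and 785 in the homozygous arrays. Both homozygous arrays lay on a second slide, while the wild-type and heterozygous arrays shared the first slide, so slide and homozygous genotype cannot be told apart. The number of arrays limits the precision of every comparison. The labels speak of 2 independent experiments per genotype but do not identify the parents or litter of each embryo. P-values of single genes therefore measure only the spread between these samples. Those of camera at its preset correlation and of permutations over genes rest on spread across genes, and do not measure spread between embryos.

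Stat3 mRNA itself was well above background in all genotypes, and no comparison of its level passed the test. Its brighter probe read 0.92 and 0.93 on the normalized log2 scale in the wild-type embryos, 1.16 and 0.92 in the heterozygous embryos, and 1.51 and 1.21 in the homozygous embryos. Stat3 was thus 0.43 ± 0.16 (log2, SE, n = 2 per genotype) above wild type in homozygous embryos, with an adjusted p of 0.0839 in limma's test. The corresponding differences were 0.11 ± 0.16 for heterozygous against wild type (adjusted p = 1.00) and 0.32 ± 0.16 for homozygous against heterozygous (adjusted p = 0.176). The homozygous excess passed the threshold in limma's test after normexp background correction with the 75th percentile (0.42, adjusted p = 0.0387) or with quantile normalization (0.40, adjusted p = 0.0417). Without homozygous replicate 2 it was 0.58 (adjusted p = 0.0381), a p that rests on the spread within the other genotypes because 1 homozygous embryo remains, and it was 0.29 without homozygous replicate 1 (adjusted p = 0.196). The dimmer probe read −4.32 and −4.36 in wild type and −4.69 and −3.40 in homozygous embryos, so 1 homozygous embryo lay below wild type (difference 0.29, adjusted p = 0.597 with every probe tested). A substitution of 2 residues leaves the transcript in place, so this measurement is no check on the genotype labels.

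**Figure D1:**
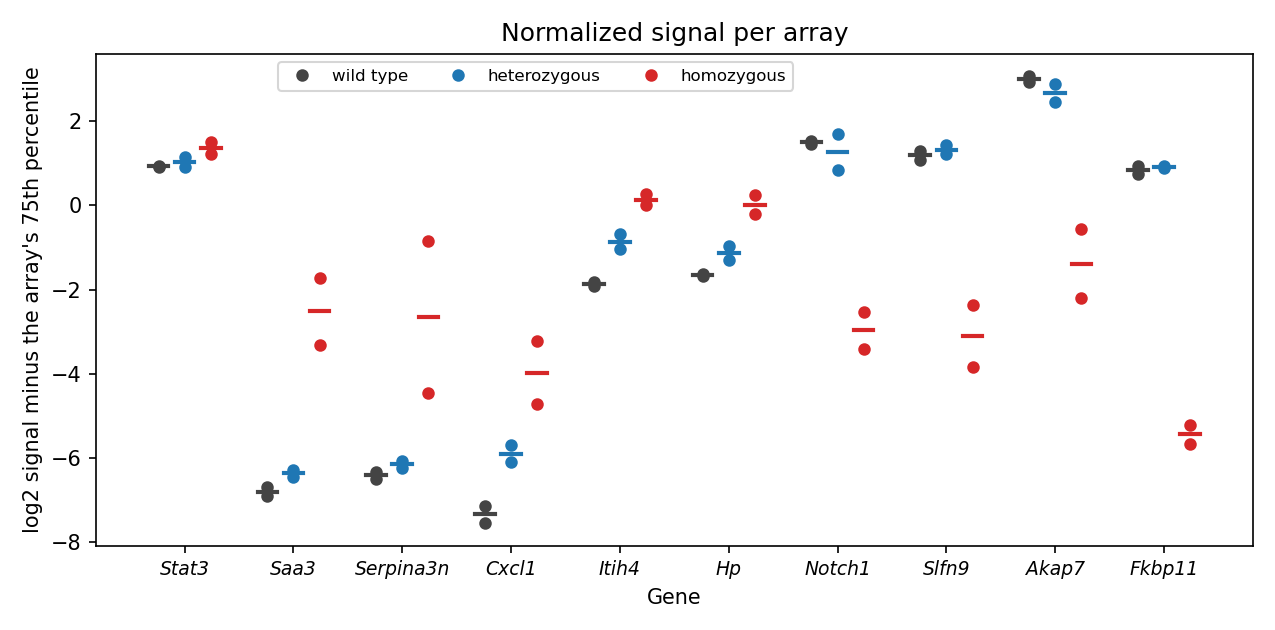
Normalized log2 signal (array signal minus the array's 75th percentile) of 10 genes in 6 embryos. Each point is 1 array and each bar the mean of the 2 arrays of a genotype, with Saa3 and Cxcl1 in wild type and Fkbp11 on 1 homozygous array not well above background.

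Homozygous embryos differed from wild-type embryos in a large part of the measured transcriptome. Saa3, a serum amyloid A protein induced in inflammation, rose by 4.28 ± 0.47 on the log2 scale (SE, n = 2 per genotype, limma's adjusted p = 0.00256). Its signal was not well above background in wild type, so the rise is stated as at least 16.6-fold. Such a bound sets the mean of the brighter genotype against the lowest signal that counted as well above background on the dimmer genotype's arrays, or the probe's own signal where that was higher. Serpina3n, an acute-phase protease inhibitor, rose by 3.76 ± 1.03 (adjusted p = 0.0396), and Cxcl1, a chemokine that attracts neutrophils, by 3.36 ± 0.47 (at least 6.03-fold, adjusted p = 0.00526). Cd177, a surface protein of neutrophils, rose by 3.05 (at least 2.52-fold). Also higher were Sbspon (3.61, at least 2.66-fold), Tmem72 (3.12) and the vomeronasal receptor Vmn1r80 (3.0, at least 1.96-fold). Saa3, Cxcl1, Cd177, Sbspon and Vmn1r80 were not well above background in wild type. The background was itself higher on the homozygous arrays, with negative controls at 43.5 and 48 against 26 in wild type. A contribution of background to these dim rises therefore stays open. The forebrain homeobox gene Gsx2 (3.36), the olfactory receptor Olfr173 (3.30) and the carboxylesterase Ces5a (3.22) rose from a wild-type signal that was well above background on only 1 of 2 arrays, so the size of their rise is uncertain. Gsx2 was also higher at a second probe (1.75, adjusted p = 0.04).

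Genes of several functions fell in homozygous embryos. Fkbp11, a prolyl isomerase of the secretory pathway, was at −6.28 ± 0.18 on the log2 scale (limma's adjusted p = 0.000434). It was measured by 1 kept probe, with signal well above background on 1 of the 2 homozygous arrays. After normexp background correction with the 75th percentile it was at −4.18. Notch1, the receptor that maintains neural progenitors, fell at both of its probes, by −4.46 ± 0.37 at the brighter and −1.59 at the other. Slfn9 likewise fell at both probes (−4.28 and −3.35). Chat, the enzyme that makes acetylcholine, was at −4.58, the lactate and pyruvate transporter Slc16a7 at −4.26 and Iqcf4 at −4.12, each measured by 1 kept probe. Coagulation factor gene F10 (−5.07), the ion channel gene Trpm1 (−4.67) and the kinase anchor gene Akap7 (−4.38) fell at their brightest probes only. The second probes of F10 and Trpm1 read 0.29 and 0.59, neither past the threshold, and the other probes of Akap7 read 0.18 and, past the threshold, 0.42.

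The size of these changes depended on single embryos and on background correction. Among the named genes, the call was lost in limma's test without wild type replicate 1 for Serpina3n (adjusted p = 0.149), Gsx2 (0.204), Ces5a (0.0588), Cd177 (0.0936) and F10 (0.0623). Without wild type replicate 2 it was lost for Serpina3n (adjusted p = 0.144), Gsx2 (0.0740), Ces5a (0.183) and F10 (0.0685). Without homozygous replicate 2 it was lost for Gsx2 (adjusted p = 0.0749) and Ces5a (0.0946), and without either heterozygous array for Serpina3n (0.0719) and Gsx2 (0.0806), whose differences are then the same by construction, with fewer arrays behind the spread. Without a wild-type array the difference was 3.69 or 3.83 for Serpina3n and −5.07 or −5.06 for F10, while for Gsx2 it was 2.44 or 4.29, for Ces5a 4.09 or 2.35 and for Cd177 2.47 without wild type replicate 1. The homozygous embryos also differed from each other, and without replicate 1 or 2 of that genotype the difference was 5.57 or 1.95 for Serpina3n, 4.80 or 1.93 for Gsx2, 4.16 or 2.28 for Ces5a, 3.99 or 2.11 for Cd177, 5.07 or 3.49 for Saa3, 4.11 or 2.61 for Cxcl1 and 3.81 or 2.42 for Tmem72. For the falls it was −6.67 or −3.46 for F10, −5.30 or −3.85 for Chat, −5.21 or −3.55 for Akap7 and −5.02 or −3.55 for Slfn9. Normexp background correction with the 75th percentile also gave smaller values for all 10 named rises, 1.92 for Serpina3n, 1.85 for Saa3, 1.60 for Tmem72, 1.59 for Gsx2, 1.43 for Olfr173, 1.15 for Ces5a, 1.08 for Cxcl1, 0.74 for Sbspon, 0.71 for Cd177 and 0.69 for Vmn1r80. Among the falls it gave −3.40 for Chat, −3.51 for Slfn9, −3.76 for Notch1, −4.00 for Trpm1, −2.72 for Slc16a7 and −2.22 for Iqcf4. All of these still passed, but their size and the fold bounds hold only without this correction. With quantile normalization after normexp, calls were lost for Serpina3n (1.78, adjusted p = 0.128), Cd177 (0.43, adjusted p = 0.163), Gsx2 (1.47, adjusted p = 0.0741) and Ces5a (0.94, adjusted p = 0.0643). Over all settings, the call was lost in 10 of 16 for Gsx2, 8 of 16 for Ces5a and 7 of 17 for Serpina3n.

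Of the gene lists, the acute-phase proteins, which the liver releases in inflammation, had the smallest p in the comparison of homozygous and wild-type embryos. Of 23 measured members, 15 rose, 1 fell and 7 did not pass the test over all genes, and 19 rose and 1 fell when adjusted over the list alone. Over all genes 28.9% were called in this comparison, the share to set beside the counts of this and the following lists. The members with the smallest p were Itih4 (2.01 ± 0.17, with 2.08 at its second probe), Saa3, haptoglobin (Hp, 1.66 ± 0.20) and ceruloplasmin (Cp, 1.95 ± 0.27). The member that fell was Saa2 (−1.05), singled out after its value was seen. The median member was 1.26 higher (log2), and the mean of the list lay 1.34 and 1.56 above the wild-type mean in the 2 homozygous embryos. By limma's camera the list stood above other genes with an adjusted p of 2.48e-05, and the adjusted p was 0.940 with an estimated correlation (unadjusted p = 0.0906). With so few arrays, the version with an estimated correlation called no list in any comparison. The call held without any single array, and the median was 1.03 to 1.26 over all settings. Because the preset correlation treats genes as nearly independent, a call kept in this way does not measure spread between embryos.

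Fetal hepatocyte markers had a median of 0.50 above wild type in homozygous embryos (limma's camera, adjusted p = 0.0209), with an adjusted p of 0.940 with an estimated correlation, and fry did not call them. Of 25 measured, 7 rose and none fell, or 11 adjusted over the list alone, among them apolipoprotein A-II (Apoa2, 0.81), alpha-fetoprotein (Afp, 0.63), kininogen (Kng1, 1.1) and Gc (0.97). The second probe of Apoa2 read 0.21. The adjusted p by limma's camera was 0.127 without homozygous replicate 1. Genes known as targets of STAT3 were higher by a median of 0.29 (adjusted p = 0.0419), a call lost with an estimated correlation (adjusted p = 0.940). Of 30, 8 rose, 1 fell and 21 did not pass, with 8 and 1 when adjusted over the list alone. Those that rose included the feedback inhibitor Socs1 (1.14 ± 0.17), the oncostatin M receptor Osmr (0.84 ± 0.13) and Bcl3 (1.01 ± 0.18), while Junb was at least 1.34-fold lower (log2 −0.62), not well above background in homozygous embryos. The call on the STAT3 targets was lost without wild type replicate 1 (adjusted p = 0.0947) and without homozygous replicate 1 (0.151). Components of the JAK-STAT pathway did not shift as a group (median 0.06, adjusted p = 0.978). Of 36, 5 rose and 6 fell, or 6 and 6 adjusted over the list alone. The called shares of hepatocyte markers, STAT3 targets and JAK-STAT components were near the share over all genes (28.9%). Il11 (1.57), Osmr and Stat4 (0.63) were higher and the coactivator Crebbp (−1.90 ± 0.13) was lower.

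Interferon response genes were higher by a median of 0.78 in homozygous embryos (adjusted p = 0.0209 by limma's camera, and 0.940 with an estimated correlation). Of 24, 9 rose, 1 fell and 14 did not pass, with the same 9 and 1 counts adjusted over the list alone, and Gbp2 (1.35), Irgm1 (1.08, with 0.92 at a second probe), Bst2 (1.07) and Ifitm3 (0.79) had the smallest p. The homozygous embryos differed from each other here, with list means of 1.09 and 0.35 above wild type, and the adjusted p was 0.102 without wild type replicate 1 and 0.169 without homozygous replicate 1. Chaperones and genes of the unfolded protein response were higher by a median of 0.37 (adjusted p = 0.0419, and 0.940 with an estimated correlation), with 7 of 24 risen and none fallen, or 8 adjusted over the list alone. Hsp90b1 (1.21), Manf (0.85) and Hspa5 (0.68), which act in the endoplasmic reticulum, led this list together with Xbp1 (0.58). Its adjusted p was 0.0947 without wild type replicate 1 and 0.127 without homozygous replicate 1. Hox genes, which pattern the body axis and limbs, had a lower median, −0.33 (adjusted p = 0.000750, and 0.940 with an estimated correlation). Of 38, 9 fell and none rose, or 8 adjusted over the list alone, among them Hoxa2 (−1.11), Hoxc11 (−1.93), Hoxd4 (−0.68) and Hoxa10 (−0.68). Their means were −0.21 and −0.71 in the 2 homozygous embryos, and the median was −0.17 (adjusted p = 0.0515) without homozygous replicate 2. Lens crystallins had a median of 1.42 (adjusted p = 0.0419, and 0.940 with an estimated correlation), although of 16 only Cryab (0.95) rose, over all genes and adjusted over the list alone. Wild-type embryos already spanned −0.89 to 0.89 in the mean of the crystallins, and the median was 2.53 without wild type replicate 2. The call was lost without wild type replicate 1 (median 0.32, adjusted p = 0.266), homozygous replicate 1 (0.169) or homozygous replicate 2 (0.0814).

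**Figure D2:**
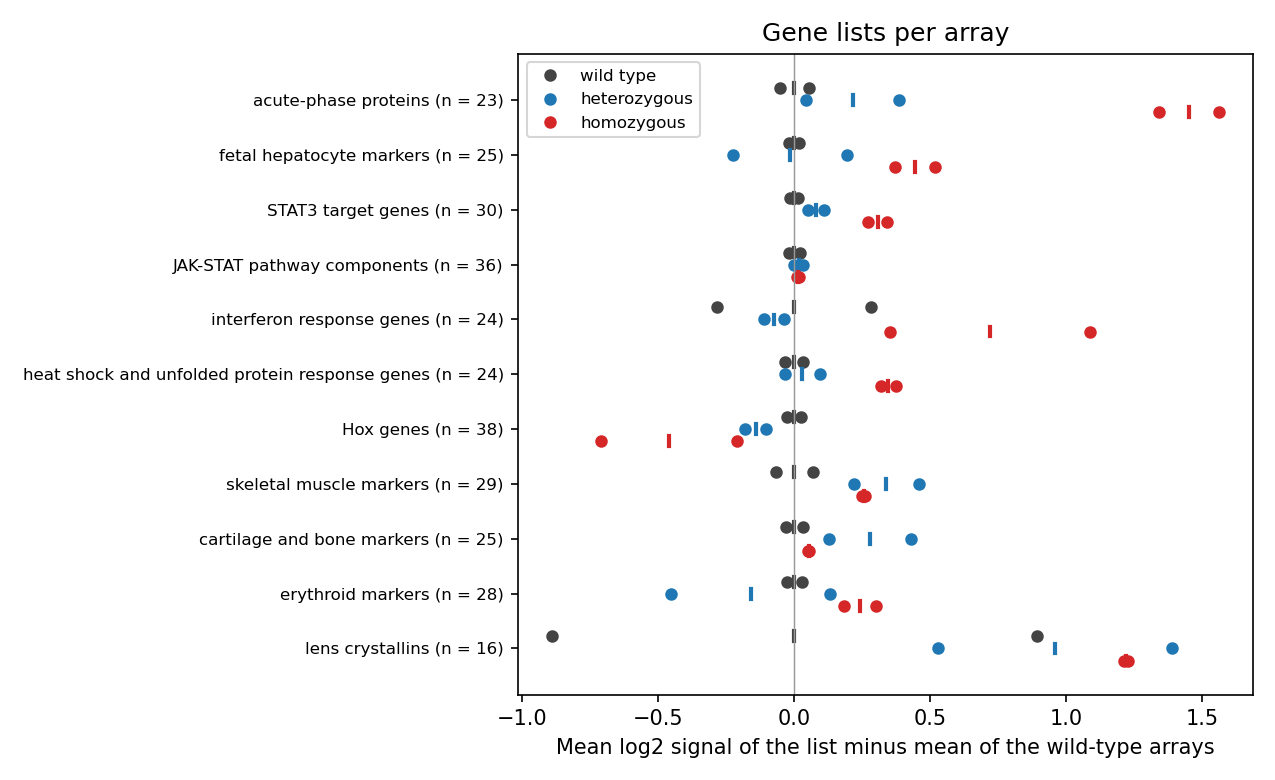
Mean normalized log2 signal of 11 gene lists in each of 6 arrays, minus the mean of the 2 wild-type arrays. Points are arrays and bars genotype means; acute-phase proteins lie at 1.34 and 1.56 in the homozygous arrays, interferon response genes at 1.09 and 0.35, and JAK-STAT components near 0, while the wild-type arrays span −0.89 to 0.89 for lens crystallins.

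Over all 24572 genes tested, limma called 7110 changed between homozygous and wild-type embryos, 3583 higher and 3527 lower, at an adjusted p below 0.05. Of these, 2493 differed at least 2-fold, 823 higher and 1670 lower. The arrays of the genotypes did not overlap for 69.6% of genes, against 33.3% by chance. Of 29 lists tested, 7 were called by camera with its preset correlation, 0 with an estimated correlation, and 5 by fry, which asks only whether the genes of a list move one way. Those 5 were the acute-phase proteins, STAT3 targets, the unfolded protein response and, beyond the 7, p53 targets and immediate early genes. With normexp background correction and the 75th percentile, or with no filter on dim probes, 2 lists were called, the acute-phase proteins and Hox genes, and with the second brightest probe of each gene none of the 5 lists among the 7 that had enough such probes, while acute-phase proteins and Hox genes had too few to be tested. Over all settings the call was lost in 1 of 19 for acute-phase proteins, 2 of 19 for Hox genes, 5 of 20 for hepatocyte markers, 6 of 20 for interferon response genes, 7 of 20 for STAT3 targets, 8 of 20 for chaperones, with 1 more turned, and 9 of 20 for crystallins. The count of genes fell to 2121 without wild type replicate 1 and to 1848 without wild type replicate 2. Normexp background correction with the 75th percentile moved the median of all genes from 0.09 up by a further 0.11 and the share of calls that were higher from 50.4% to 69.5%, while with quantile normalization after normexp the median was 0.05 and the share 53.1%.

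Different probes of the same gene often told different stories. In 4435 genes with at least 2 kept probes, the homozygous minus wild type differences of the 2 brightest probes correlated at r = 0.108 across genes, which are not independent replicates, and had the same sign in 54.3%. At least 1 probe was called in 2022 of these genes, all probes were called in one direction in 158 (79 higher and 79 lower), and probes were called in opposite directions in 174. Calls in one direction were thus no more frequent than calls in opposite directions. With every probe tested, 4017 of 29906 were called higher and 4253 lower. Agreement of 2 probes therefore does not by itself establish a change in a gene. The same probe pairs correlated more closely, at r = 0.375, for heterozygous minus wild type differences. Genes with concordant calls included Itih4, Irgm1, Kng1 and Gsx2 among the rises and Notch1 and Slfn9 among the falls. Aqp4, the water channel of glia, was −1.08 at one probe and 1.22 at another.

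**Figure D3:**
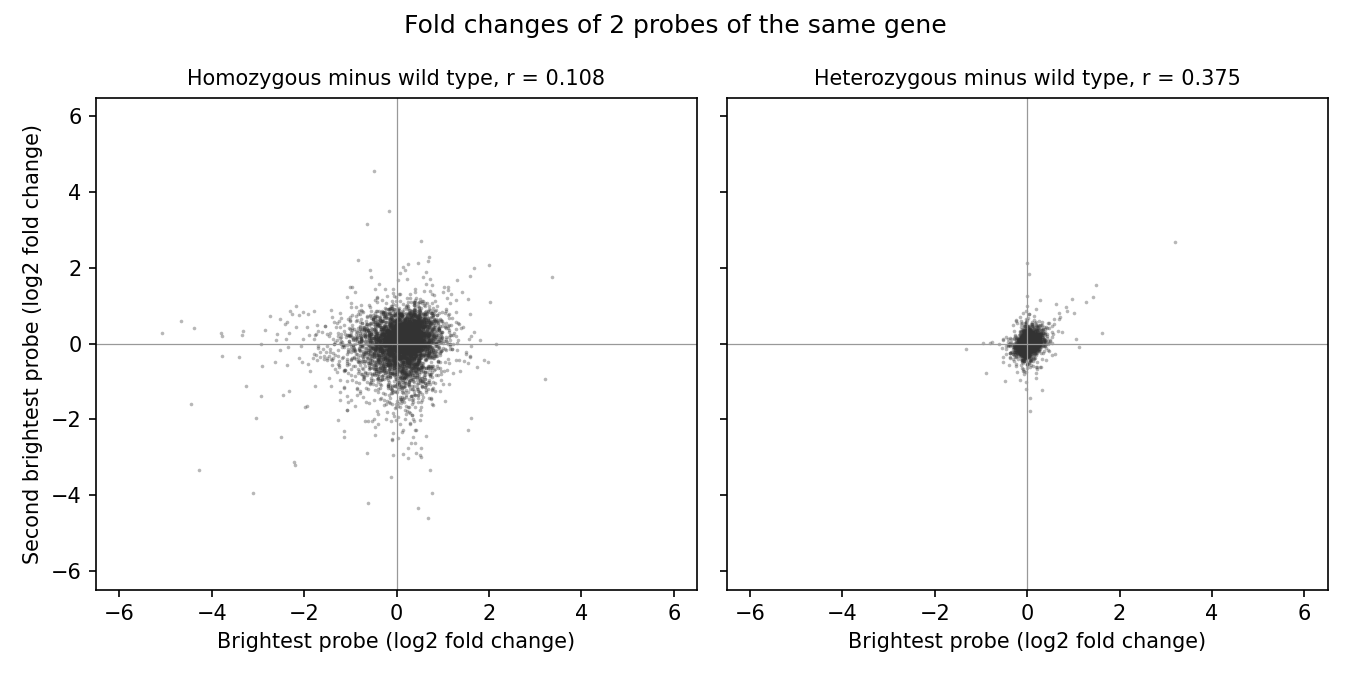
Log2 fold change of the brightest probe (horizontal) against that of the second brightest probe (vertical) for 4435 genes, 1 point per gene, for homozygous minus wild type (left, r = 0.108) and heterozygous minus wild type (right, r = 0.375). Many large homozygous differences lie near an axis, where 1 probe differs more than the other, while genes such as Slfn9 lie off the axes with both probes lower.

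Heterozygous embryos resembled wild-type embryos closely, and limma called 0 of 24572 genes changed. At an unadjusted p below 0.05 there were 540 genes, where chance gives 1229, and the smallest adjusted p was 0.166. The shared fit takes in the spread of the homozygous pair, whose arrays differed more from each other. The SD of that difference was 0.48, against 0.28 in wild type and 0.30 in heterozygous embryos. In a fit of the 2 genotypes alone there were 1048, so the 540 do not show an unusually close resemblance. The genes closest to the threshold were Bpifa1, a secreted protein of the airway (1.97 ± 0.15, SE, n = 2 per genotype, limma's adjusted p = 0.166), and the vomeronasal receptor Vmn1r213 (−2.86 ± 0.23, at least 1.60-fold lower, adjusted p = 0.166). None of the following values passed the test, each with an adjusted p of 1.00 in limma. Above wild type were Akr1b7 (1.27), the muscle creatine kinase Ckm (1.09), the acute-phase gene Itih4 (1.01, with 0.81 at its second probe), the bone sialoprotein Ibsp (0.97, with 1.16 at its second probe), Wfdc17 (0.86), Serpini2 (0.81, at least 1.34-fold), Atp1b4 (0.74) and Agr2 (0.69). Ccn6 was not well above background in either genotype. Below wild type were Vmn2r5 (−2.86, at least 2.93-fold), the limb patterning genes Hoxd13 (−1.0) and Hoxd12 (−0.93), Ido2 (−0.94), Adam24 (−0.92), Stk32c (−0.92), Defb26 (−0.89), Klhdc8a (−0.61, at least 1.25-fold) and Rad9b (−0.57, at least 1.31-fold). The dim genes among these depended on background correction, and after normexp with the 75th percentile Serpini2 was at −0.03, Bpifa1 at 0.52, Vmn1r213 at −0.51, Vmn2r5 at −0.70, Klhdc8a at −0.30, Rad9b at −0.30, Wfdc17 at 0.09, Agr2 at 0.12, Ckm at 0.61, Atp1b4 at 0.52, Ido2 at −0.28, Adam24 at −0.39, Stk32c at −0.37 and Defb26 at −0.41.

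Lists of tissue genes nevertheless had small differences between heterozygous and wild-type embryos, and limma's camera called 14 of 29 lists with its preset correlation. None was called with an estimated correlation (lowest adjusted p = 0.555) or by fry. For immediate early genes camera's unadjusted p rose from 0.00115 to 0.0374 with an estimated correlation, although the estimate, −0.018, lay below the preset. The lack of calls therefore does not by itself show that members of a list vary together. Skeletal muscle markers were higher by a median of 0.31 (adjusted p = 9.37e-18), led by Ckm, Tnnt3 (0.58), Myf6 (0.76) and Mylpf (0.68). Cardiac muscle markers were higher by 0.29 (adjusted p = 1.09e-07), with Myl3 at 0.63 and Myh7 at 0.64, and cartilage and bone markers by 0.23 (adjusted p = 1.58e-08), with Ibsp at 0.97 and the hypertrophic cartilage collagen Col10a1 at 1.40. The median of cartilage and bone markers was 0.09 without heterozygous replicate 1 and 0.40 without heterozygous replicate 2, and the call was lost with the second brightest probe (−0.00942, adjusted p = 0.588). That of skeletal muscle markers was 0.18 without heterozygous replicate 1, and that of cardiac muscle markers 0.19 without wild type replicate 2. Lens crystallins were higher by 1.07 (adjusted p = 1.34e-09), but their median was −0.00418 without wild type replicate 1 (adjusted p = 0.569), 2.16 without wild type replicate 2 and 0.52 without heterozygous replicate 1. Smaller medians above wild type were those of macrophage markers (0.15, adjusted p = 0.000161), epithelial markers (0.12, 0.000161), placenta markers (0.15, 0.0358), extracellular matrix genes (0.08, 0.00259) and immediate early genes (0.07, 0.00277). Acute-phase proteins were higher by 0.17 (adjusted p = 0.00203), but their median was −0.07 without heterozygous replicate 2 (adjusted p = 0.365) and −0.02 after normexp background correction with the 75th percentile. STAT3 targets were higher by 0.07 (adjusted p = 0.00757), and lost the call without wild type replicate 1 (0.178) and without heterozygous replicate 2 (0.327). Medians below wild type were those of erythroid markers (−0.19, adjusted p = 0.000603), Hox genes (−0.07, adjusted p = 0.00203) and ribosomal protein genes (−0.08, adjusted p = 0.000680). That of erythroid markers turned to 0.10 without heterozygous replicate 1, and that of ribosomal protein genes to 0.01 under quantile normalization. The Hox median spanned −0.16 to −0.04 over all settings, and its call was lost without heterozygous replicate 2. The calls also ended for macrophage markers without heterozygous replicate 2 (adjusted p = 0.327), extracellular matrix genes without wild type replicate 2 (0.173) or heterozygous replicate 1 (0.393), immediate early genes without heterozygous replicate 2 (0.0846), ribosomal protein genes without wild type replicate 1 (0.280) or heterozygous replicate 2 (0.108), and placenta markers without each of 5 arrays (0.594 at most) and in 13 of 20 settings in all. No member of these 14 lists passed over all genes, and Ckm, Ibsp, Itih4, Hoxd13 and Hoxd12 passed adjusted over their list alone.

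This comparison lay within the first slide, and a fit restricted to that slide also called 0 genes (1048 at an unadjusted p below 0.05) and 13 lists. On that slide the heterozygous arrays held positions 1 and 2 and the wild-type arrays positions 3 and 4. Position on the slide and genotype therefore cannot be told apart in this comparison. Leaving out single arrays gave 4 genes without wild type replicate 1, 9 without wild type replicate 2 and 5 without heterozygous replicate 2. In simulated data the same test recovered 47.8% of genes changed 2-fold between heterozygous and wild type, so changes of that size were detectable in part only.

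Homozygous embryos differed from heterozygous embryos in much the same large genes as from wild type, with which the comparison shares its homozygous arrays. Saa3 rose by 3.84 ± 0.47 (log2, SE, n = 2 per genotype, limma's adjusted p = 0.00418), Sbspon by 3.67 (at least 2.83-fold), Vmn1r80 by 2.73 (at least 2.09-fold) and Tmem72 by 2.57. The sensory receptor genes Olfr767 (3.23, with heterozygous signal well above background on only 1 of 2 arrays, so its size is uncertain), Olfr780 (2.94, at least 3.51-fold), Olfr1134 (2.85) and Vmn1r222 (2.36), and Mfsd4b5 (2.48) and Tmem266 (2.43), were also higher. Fkbp11 was at −6.34 ± 0.18 (adjusted p = 0.000439) and at −4.26 after normexp background correction with the 75th percentile, which also gave 1.99 for Saa3, 0.94 for Sbspon, 0.83 for Vmn1r80, 1.55 for Tmem72, 1.24 for Olfr767, 1.0 for Olfr780, 2.28 for Olfr1134, 1.63 for Vmn1r222, 1.77 for Mfsd4b5 and 2.04 for Tmem266, so the fold bounds hold only without it. Without homozygous replicate 1 or 2 the difference was −6.36 or −3.16 for F10, 4.63 or 3.05 for Saa3, 4.45 or 2.01 for Olfr767, 3.26 or 1.87 for Tmem72, 1.75 or 2.97 for Vmn1r222, −5.16 or −3.68 for Slfn9, −5.03 or −3.59 for Chat and −4.89 or −3.23 for Akap7. The largest falls also included F10 (−4.76), Trpm1 (−4.43), Slfn9 (−4.42), Chat (−4.31), Notch1 (−4.23), Slc16a7 (−4.17), Akap7 (−4.06) and the zinc finger gene Zfp345 (−4.02). Normexp with the 75th percentile gave −2.66 for Slc16a7, −3.15 for Chat, −3.25 for Zfp345 and −3.59 for Slfn9. It gave −3.61 for Notch1, −3.78 for Trpm1, −3.79 for Akap7 and −4.63 for F10. The other probes of F10, Trpm1 and Akap7 again lay above 0. In limma's test Olfr767 lost its call in 12 of 16 settings, among them without each of 5 arrays (adjusted p = 0.199 at most) and after normexp with quantile normalization (0.81, adjusted p = 0.0915). So did Tmem72 without heterozygous replicate 1 (0.0514) or 2 (0.0649), F10 without heterozygous replicate 1 (0.0963) or 2 (0.0671), and Vmn1r222 without heterozygous replicate 2 (0.0613).

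Limma's camera called 8 lists between homozygous and heterozygous embryos, and none with an estimated correlation, where all 8 had an adjusted p of 0.840, or by fry. Acute-phase proteins had a median of 1.06 above heterozygous embryos (adjusted p = 0.000116). Of 23, 13 rose and 1 fell, or 17 and 1 adjusted over the list alone, and besides Saa3 the smallest p were those of the iron-binding lipocalin Lcn2 (1.49), Hp (1.13) and Itih4 (1.00). Interferon response genes were higher by 0.84 (adjusted p = 0.00798; 8 rose and 1 fell, or 10 and 1 adjusted over the list alone), with Gbp2 at 1.2 and Bst2 at 1.15. Fetal hepatocyte markers were higher by 0.60 (adjusted p = 0.0146; 6 rose, or 8 adjusted over the list alone), with Afp at 0.76. Erythroid markers were higher by 0.44 (adjusted p = 0.0339; 4 rose, or 3 adjusted over the list alone), with the adult beta-globin Hbb-bt at 1.43 and Hba-a2 at 0.72. Cell cycle genes were higher by 0.36 (adjusted p = 0.0290; 11 rose and 1 fell, or 13 and 1 adjusted over the list alone), with Tyms at 0.97, Cdc20 at 1.01 and Ccnb2 at 0.95. Unfolded protein response genes were higher by 0.35 (adjusted p = 0.0290; 5 rose, or 7 adjusted over the list alone), again with Hsp90b1 (1.03) and Manf (0.67). Ribosomal protein genes were higher by 0.29 (adjusted p = 0.0290; 13 rose and 3 fell, or 17 and 6 adjusted over the list alone), at −0.00231 after normexp with quantile normalization. The median of Hox genes was −0.24 (adjusted p = 0.0167; 2 rose and 4 fell, also adjusted over the list alone), with Hoxa2 at −1.04 and Hoxd12 at 1.15.

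Of these 8, camera called 3 after normexp background correction with the 75th percentile (acute-phase proteins, interferon response genes and Hox genes), 2 with no filter on dim probes (acute-phase proteins and Hox genes), and 5 with every probe tested. With the second brightest probe it called none, but acute-phase proteins, Hox genes and erythroid markers had too few such probes to be tested. Over all settings the call on erythroid markers was lost in 9 of 19, among them quantile normalization (adjusted p = 0.107), the authors' values (0.106), normexp with the 75th percentile (0.490) or quantiles (0.0867), no filter on dim probes (0.170) and every probe (0.0664). The call was lost in 9 of 20 for ribosomal protein genes and 7 of 20 for chaperones, each with 1 more turned, 7 of 20 for cell cycle genes, 6 of 20 for hepatocyte markers and 4 of 20 for interferon response genes. Without homozygous replicate 1 the calls were kept for acute-phase proteins and Hox genes only. Without heterozygous replicate 1 the calls ended for hepatocyte markers, erythroid markers, cell cycle genes and unfolded protein response genes, and without homozygous replicate 2 for Hox and cell cycle genes. A lost call need not mean a lost difference. Over all settings the medians spanned 0.73 to 1.30 for acute-phase proteins, 0.47 to 1.11 for interferon response genes and 0.26 to 0.48 for cell cycle genes. They spanned 0.29 to 0.78 for hepatocyte markers, 0.12 to 0.73 for erythroid markers and −0.42 to −0.08 for Hox genes. Those of unfolded protein response genes spanned 0.03 to 0.45, and those of ribosomal protein genes −0.00231 to 0.33. Over all genes limma called 6021 (24.5%), of which 2902 were higher and 3119 lower, and 2101 differed at least 2-fold. The count was 3108 without either wild-type array, 1615 without heterozygous replicate 1, 2411 without heterozygous replicate 2, and 11781 after normexp background correction with the 75th percentile. That correction moved the median of all genes by 0.16 and the share of calls that were higher from 48.2% to 77.3%. Of genes with at least 2 kept probes, 1700 had a called probe, 107 had all probes called in one direction, and 124 had probes called in opposite directions.

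Across the 3 genotypes together, the moderated F-test of limma called 5465 genes, and 3341 when the number of mutant alleles was fitted as a linear term. The F-test count was 2191 without wild type replicate 1, 2049 without wild type replicate 2, 2942 without heterozygous replicate 1 and 3422 without heterozygous replicate 2. The comparisons of homozygous embryos with wild type and with heterozygous embryos shared 5476 calls in the same direction, 2586 higher and 2890 lower, where independent lists would share 871, but they also share their homozygous arrays. Across genes, heterozygous and homozygous differences from wild type correlated at r = 0.304, and simulated genotypes with no effect against the same wild-type arrays gave 0.499. That simulated value follows from shared arrays and equal spread, so an r below it does not show a lack of shared effect. The observed covariance was 0.0466 and the simulated covariance 0.0337, a difference of 0.0129. The simulated spread was pooled over genotypes, and the homozygous pair widens it (SD of the difference 0.48, against 0.28 in wild type). The difference in covariance therefore cannot measure a shared effect. With a different wild-type array for each comparison r was 0.109 or 0.174, and without heterozygous replicate 2 it was also 0.174.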

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

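The tests in this part were chosen after the result was seen.

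The homozygous arrays had a higher background than the rest, in spots outside the gene comparisons. Negative controls had a median signal of 43.5 and 48 in the homozygous arrays, against 26 at most in wild type and 27 at most in heterozygous arrays. The local background was 20 and 21, against 15.5 at most in wild type and 16 in heterozygous arrays. Their 75th percentile signals, 860 and 785, were the lowest of the 6 arrays.

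Large numbers of genes differed between homozygous embryos and the others, and both homozygous arrays lay on their own slide. With 0 arrays of other genotypes on that slide, a slide difference and the genotype cannot be told apart for any of these genes. A changed amount of whole transcripts as the whole cause was argued against: 2 probes of a gene shared 12.0% of the error-corrected variance of their differences (95% bootstrap interval 7.50 to 16.9). Lower brightness of the homozygous arrays as the whole cause was argued against for the brightest genes only, because differences were not confined to dim genes. The share of genes called at 2-fold or more was 8.04% in the brightest 25% of genes and 14.2% in the dimmest 25%. The ratio was 0.565 (95% bootstrap interval 0.510 to 0.627), judged by a cutoff set after the result was seen. The dimmest genes still had the higher share, so a contribution of brightness there stays open. A slide difference, differences in labelling or sequence between probes, and a real change in part of the genes therefore stay open, and the genotype may contribute to any of these genes.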

How the results depend on the processing

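The second brightest probe and the count of genes with all probes called in one direction were chosen after the data were seen. Of 2755 values under alternatives, 14 turned direction where a call was made in either setting, and a further 128 changed sign with no call. The causes were not tested. Scan dates were the same for all arrays and could not be fitted, and a slide block could not be fitted for homozygous comparisons.

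Of homozygous against wild type, 1848 (without wild type replicate 2) to 8869 genes (without homozygous replicate 1) were called when single arrays were left out (with 1 homozygous array the other genotypes supply all the spread), 2682 differed at least 2-fold with no test, and 158 had all probes called in one direction. Lists called numbered 2 with normexp and the 75th percentile, 2 with no dim filter, 0 with an estimated correlation, 0 with the second brightest probe (acute-phase proteins and Hox genes not tested), and 2 to 8 without single arrays. The acute-phase call was kept in 18 of 19 settings, with adjusted p of 1.23e-06 to 0.940. Stat3 was 0.42 with normexp and the 75th percentile, 0.40 with normexp and quantiles, and 0.29 to 0.58 without single arrays. For heterozygous against wild type, genes numbered 0 to 9 without single arrays and 72 at 2-fold with no test. Lists numbered 0 with an estimated correlation, 0 with fry and 4 with the second brightest probe. For homozygous against heterozygous, genes numbered 11781 with normexp and the 75th percentile, 3108 in the 2 genotypes alone, 3659 with array weights, 1615 to 7903 without single arrays, 2317 at 2-fold with no test and 107 with all probes called one way. Lists, not all among the 8, numbered 5 with normexp and the 75th percentile, 3 with no dim filter, 5 with every probe, 0 with an estimated correlation, 0 with fry, 0 with the second brightest probe (acute-phase proteins, Hox genes and erythroid markers not tested) and 2 to 12 without single arrays. The F-test called 9731 genes with normexp and the 75th percentile, 3339 with array weights, 3341 with the number of alleles and 2049 to 6558 without single arrays. The correlation of differences was 0.149 with normexp and the 75th percentile, 0.244 with no dim filter and 0.174 to 0.370 without single arrays.

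The median of ribosomal protein genes in heterozygous against wild type was 0.0140 with quantile normalization, 0.0247 with normexp and quantiles and 0.0140 with the authors' values, and in homozygous against heterozygous −0.00231 with normexp and quantiles. With the second brightest probe, relative to other genes, the tests turned for chaperone genes (medians 0.13 against wild type and 0.0259 against heterozygous) and, in heterozygous against wild type, for STAT3 targets (−0.0199), extracellular matrix genes (−0.0345) and epithelial markers (0.14). In that comparison the medians without single arrays spanned −0.17 to 0.17 for neural progenitors, −0.33 to 0.14 for interferon response genes, −0.21 to 0.19 for hepatocyte markers, −0.52 to 0.10 for erythroid markers and −0.0711 to 0.39 for acute-phase proteins.

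Replicate numbers did not pair the embryos (correlations of deviations 0.01, −0.14 and 0.24). With the replicate number as a block, 6815, 0 and 5604 genes and 6, 13 and 8 lists were called in the 3 comparisons, and 4748 genes by the F-test. A slide block has nothing to adjust in heterozygous against wild type, whose 4 arrays share a slide, and equals the fit of these 2 genotypes alone, with 0 genes in limma (1048 at an unadjusted p below 0.05) and 13 lists.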

Other observations

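The tests that weigh explanations in this part were chosen after the result was seen, while the list tests were planned.

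Several gene groups outside the called lists held individual genes that differed between homozygous and wild-type embryos (limma, n = 2 per genotype). Camera did not call these lists, while fry called p53 targets and immediate early genes. Over all genes 28.9% were called in this comparison, so lists with called members near that share do not stand out. Cell cycle genes had a median of 0.28 (adjusted p = 0.107), with 10 of 33 higher and 1 lower, and Tyms (1.09), Cdc20 (1.08), Ccnb2 (0.93) and Rrm2 (0.73) among the higher ones. Neural progenitor genes had 5 higher and 3 lower of 24 (median 0.43, adjusted p = 0.150), with Notch1 lower, Neurog1 at 1.5 and Hes1 at −0.85. Skeletal muscle genes had 7 higher and 1 lower of 29 (0.19, adjusted p = 0.150), with Mylpf at 1.54, Rapsn at 1.46 and Myf6 at 1.29. Ribosomal protein genes had 12 higher and 5 lower of 45 (0.20, adjusted p = 0.150), among them Rpl27 (1.29, and 0.20 at a second probe) and Rps10 (1.1). p53 targets had 7 higher of 24 (0.30, adjusted p = 0.144), including Bax (0.61) and Fas (0.72). Immediate early genes had 7 higher and 1 lower of 22 (0.29, adjusted p = 0.157), including Zfp36 (0.89) and Maff (0.92). Macrophage markers had 5 higher and 1 lower of 19 (0.35, adjusted p = 0.0671). Cholesterol synthesis genes had 6 higher and 2 lower of 25 (0.24, adjusted p = 0.107), with Dhcr7 at 1.04 and Fdps at −1.03, and hypoxia and glycolysis genes 7 higher and 2 lower of 32 (0.17, adjusted p = 0.207), with Pdk1 at −0.80.

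The other lists held genes that were higher, lower or both in homozygous embryos. Of 28 extracellular matrix genes (0.27, adjusted p = 0.284), 6 were higher and 3 lower, with Mfap5 at 0.95, Twist1 at −1.22 and Col5a2 at −0.83, and Prrx1 at −1.71 by its brighter probe and −0.05 by its other. Cartilage genes (0.02, adjusted p = 0.845) had 3 of 25 higher and 3 lower, with Col11a2 at −1.25, Sox5 at −0.85 and −1.17 at its probes, and Matn1 at 1.01. Placenta genes (−0.04, adjusted p = 0.532) had 2 of 12 higher and 5 lower, with Gcm1 at −2.20, −2.28 and −3.22 at its 3 probes and Ascl2 at 1.12. Epithelial genes had 5 of 24 higher (0.18, adjusted p = 0.355), including Ovol1 (1.03) and Grhl3 (0.95). Yolk sac genes had 2 of 19 higher (0.24, adjusted p = 0.254), Spink1 (0.93) and Afp, and erythroid genes 3 of 28 higher (0.24, adjusted p = 0.207). Cardiac genes had 1 of 21 higher and 2 lower (0.09, adjusted p = 0.774), with Myl3 at 1.19 and Tnni3 at −0.99. Neuron genes had 1 of 33 higher and 2 lower (0.18, adjusted p = 0.485), with Elavl3 at −1.86, and glial genes 1 of 16 higher and 2 lower (0.14, adjusted p = 0.858). Endothelial genes had 2 of 21 lower (0.11, adjusted p = 0.858). For kidney and gonad genes (median 0.06, mean −0.08, adjusted p = 0.774), with 2 of 19 higher and 2 lower, Osr1 was at −2.00, and for respiratory chain genes (median 0.07, mean −0.03, adjusted p = 0.858), with 6 of 40 higher and 5 lower, Atp5o was at −1.86. In both of these lists the median and the mean differed in sign.

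Xist was well above background in wild type embryo 1 (−0.34) and homozygous embryo 2 (−0.41) only. Ddx3y was well above background in the other 4 embryos, at 0.31 in wild type embryo 2, 0.10 and 0.41 in the heterozygous embryos and 0.13 in homozygous embryo 1. Eif2s3y and Uty had the same pattern, and Kdm5d was not above background on any array. The wild-type and the homozygous pairs thus each held embryos of both sexes, and both heterozygous embryos showed the male pattern. The embryonic globins, too few to test as a list, had differences between homozygous and wild type of −0.11 for Hbb-bh1, −0.23 for Hba-x, 0.39 for Hbb-y and −0.88 for Hbb-bh2. Between heterozygous and wild type the corresponding differences were −0.81, −0.66, −0.20 and 0.37. The correlation of arrays was 0.964 to 0.976 between homozygous and other embryos, 0.988 within the homozygous pair, and 0.995 to 0.996 among the other arrays.

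Camera called acute-phase genes higher in homozygous embryos with its preset correlation, but not with an estimated one (adjusted p = 0.940). Acute-phase genes exceeded the fetal hepatocyte markers by 0.75 in median (permutation test over genes, p = 1e-05, the smallest that 100000 permutations can give). These genes are not independent, and the p is not corrected for taking this list up among the 29 lists. How far each list is confined to liver cells was not measured, so the gap cannot decide on a larger share of liver cells. Such a larger share and a change within liver cells both stay open. Independent errors of single probes were argued against, because 22 of 23 acute-phase genes, each on its own probe, lay above 0, against at most 21 in 10000 sets of other genes matched for brightness (permutation test over genes, p = 0.0001, the smallest such sets can give, and 0.0029 times the 29 lists among which this one was taken up). The 3 other kept probes of these genes also lay above 0 (Itih4 2.08, C3 0.82 and Fga 0.85). A slide difference stays open with 0 arrays of other genotypes on the homozygous slide, so the mutant allele may or may not be what raised these genes.

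Camera called 14 lists between heterozygous and wild-type embryos with its preset correlation, but none with an estimated correlation (lowest adjusted p = 0.555) and fry none, and no single gene passed in limma (540 at an unadjusted p below 0.05). Single embryos that differ from the rest stay open as an explanation. Both heterozygous arrays lay beyond both wild-type arrays in 9 of 14 called lists, and 10 of 14 changed their call or direction without 1 array. Among single genes the arrays did not overlap in 27.5%, against 33.3% by chance. The 14 lists were taken up because they shifted in these same arrays, and some share members, which favours a high count. A call can also end with its median kept, and that of immediate early genes stayed at 0.05 to 0.10 in all settings. The median of erythroid markers, by contrast, turned to 0.10 without heterozygous replicate 1. A slightly later developmental stage stays open as well, with embryonic globins lower than in both wild-type arrays in 2 of 2 heterozygous arrays. The homozygous arrays also lay below both wild-type arrays (−0.15 and −0.27 against −0.13 for the lower wild-type array). Hbb-bh2 was higher in heterozygous embryos (0.37), and erythroid markers as a whole were at −0.45 and 0.13 in the 2 heterozygous arrays. The globins are therefore weak evidence of stage. Sex, litter and position in the womb were not tested, and array position on the slide cannot be told apart from genotype here.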
